A study of Mus musculus with 48 samples.

How the data were processed

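The deposited table holds raw counts per Ensembl gene, 1 column per library, for 48 brain hemisphere libraries prepared with a kit that primes at the transcript 3' end. Per the submitters' processing notes, the authors worked with bcl2fastq, STAR 2.7.3a, featureCounts, Subread 2.0.0 and DESeq2 1.28.1 on the mm10 build, and neither the annotation release nor the strand setting is given. The values were checked to be whole numbers at or above 0. Libraries of a group were tested for copies: 121 pairs within groups had a chi-square per degree of freedom of 2.29 to 18.8, and 0 were identical. The table had 55487 entries, of which 346, with 0.0154% of the counts, matched no gene symbol in GENCODE M21 (GRCm38) by Ensembl identifier. The submitters' table had no entry for human SIGLEC11.

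Libraries were grouped by genotype and treatment as the labels give them. In the SIGLEC11 LPS with polySia group 1 column carries a number that matches no sample label, so its group is known and its sample is not; it is called the unnumbered library. The labels describe the libraries as separate animals and give no batch, sequencing date or pairing.

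Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 8 groups (minimum count 10, minimum total count 15), libraries were scaled by TMM, and 1 model with a mean per group was fitted to all 48 libraries (estimateDisp and glmQLFit, robust). Each comparison was a contrast of that model, tested by edgeR's quasi-likelihood test, and genes with a Benjamini-Hochberg adjusted p below 0.05 are called. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The p-values treat each library as a replicate. Comparisons were LPS against PBS, LPS with polySia against LPS and against PBS, and polySia against PBS in each genotype, SIGLEC11 against wild type averaged over the treatments, and the differences between genotypes in the LPS effect and in the polySia effect on LPS. CPM use TMM-scaled library sizes. Where a group held 0 counts the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts a ratio with a 95% counting interval.

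Genes are named by a rule set in advance: up to 8 higher and 8 lower called genes per comparison with the largest log2 fold change and a mean of 1 CPM or more, without unnamed loci, filled up to 4 per direction with the smallest unadjusted p; the 3 members of smallest p of up to 4 lists past the camera threshold; and a panel of 14 genes told as a group. Near-identical genes share reads, so the split between C4b and its copy, Lyz2 and its copy, the Ms4a6 genes, the H2 genes and the immunoglobulin genes is less certain than their sum.

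A set of 37 gene lists for pathways, cell types and brain regions was written in advance and tested by camera of limma 3.58.1 (preset correlation 0.01, at least 5 tested members), then with the correlation estimated per list and by fry, which tests whether members move together without comparing them with other genes. Members of several lists overlap, and brain tissue expresses most members. The LPS score is the mean over signature genes of the log2 CPM (prior count 2) minus the PBS mean, with the sign of the gene's LPS effect in the other genotype. Groups were compared by exact permutation of the libraries, and intervals invert that test.

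Alternatives were DESeq2 1.42.0, limma with library weights, RLE size factors, no low-count filter, a stricter filter (1 CPM in 24 libraries), only the compared groups, the replicate number as a block, 2 surrogate variables from sva 3.50.0, other score genes, and each library left out in turn. After the data were seen, 2 more were added: leaving out the 5 libraries with a first principal component above 30 together, and a covariate that is not reported here but is counted among the settings. For each comparison 100 splits of the same libraries, the real one included, were refitted.

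The pipeline was tested on simulated data with 16619 genes and 50 changed genes at each fold. With the wild-type LPS and PBS group sizes edgeR recovered 22% of genes changed 1.25-fold, 58% at 1.5-fold, 86% at 2-fold and 96% at 4-fold, with 6 false among 137 calls. For LPS with polySia against LPS it recovered 92% at 2-fold in wild-type and 70% in SIGLEC11 group sizes, and 74% for the difference between genotypes. At 1.25-fold it recovered 22% and 34% in these group sizes. Each comparison was simulated once with its own changed genes, so such gaps are not due to group size alone. Genes were simulated independently, without the variation that real libraries share. Of 30 simulated lists the raised one was called and 1 other was called too. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.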

Results

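RNA from the left brain hemisphere of male C57BL/6J mice, 3 months old, was sequenced from transcript 3' ends on day 19 after 4 daily intraperitoneal injections. The mice were wild type or carried human SIGLEC11, an inhibitory receptor of microglia that binds sialic acid. They received PBS, lipopolysaccharide (LPS, a bacterial inflammatory stimulus, 1 µg per g per day), low-molecular-weight polysialic acid (polySia, a sialic-acid chain, 10 µg per g) or LPS with polySia. The wild-type groups held 6 PBS, 6 polySia, 6 LPS and 7 LPS with polySia libraries, and the SIGLEC11 groups 6, 6, 6 and 5, each from a separate animal. The 48 libraries held 5453797 to 10409228 counts (median 8120077), and 16619 genes were tested. With no effect, about 1 in 20 of the tested genes would have an unadjusted p under 0.05. Group means ran from 7552387 ± 1305789 counts (SD, n = 6) in SIGLEC11 PBS to 8656788 ± 997245 (n = 6) in SIGLEC11 LPS. Log2 fold changes are given with their standard error and an adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Levels are CPM (counts scaled to the library size) with their SD. Counting intervals and floors cover counting error only. The count table had no SIGLEC11 entry, so the level of the transgene was not measured.

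In wild-type mice, LPS raised microglial, antigen-presentation and complement transcripts 19 days after treatment. Cd52, a surface protein of immune cells, rose from 2.23 ± 0.6 to 8.42 ± 1.51 CPM (n = 6 and 6, log2 fold change 1.91 ± 0.26, adjusted p = 5.12e-06, edgeR). The lysozyme Lyz2 rose from 9.54 ± 1.64 to 25.8 ± 5.02 CPM (1.43 ± 0.18, adjusted p = 2.39e-06), and the MHC class II chains H2-Aa (1.38 ± 0.23) and H2-Eb1 (1.49 ± 0.21) rose with their invariant chain Cd74 (1.36 ± 0.25). The complement subunits C1qa (0.82 ± 0.12, adjusted p = 1.81e-05), C1qc (0.64 ± 0.10) and C1qb (0.54 ± 0.10) rose less, as did the microglial transcripts Aif1 (0.99 ± 0.14), Tyrobp (0.65 ± 0.11), Fcer1g (0.68 ± 0.12) and Ctss (0.63 ± 0.081, adjusted p = 1.01e-06). All of these 12 genes were higher in 6 of 6 LPS libraries than in every PBS library, and each kept its call in all 22 alternatives and leave-outs. Saa3, an acute-phase protein, had 0 counts over the PBS libraries and 231 over the LPS libraries, at least 77.5-fold higher against a floor of 3 counts over the group.

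LPS called 27 genes in wild-type mice, 26 higher and 1 lower, out of 793 genes at unadjusted p under 0.05. The 793 genes are no more than would be expected with no effect. Transcripts that rose with calls lost in some alternatives were the immunoglobulin light chain Igkc (3.29 ± 0.58, adjusted p = 0.00183, above every PBS library in 6 of 6), the receptor Tlr2 (1.98 ± 0.41, 5 of 6) and complement C3 (1.67 ± 0.37, 6 of 6). Their calls held in 20 of 22, 18 of 21 and 18 of 22 alternatives and leave-outs. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose from 1.66 ± 0.634 to 3.88 ± 1.08 CPM (1.24 ± 0.29, adjusted p = 0.0369, above every PBS library in 5 of 6), and its call held in 11 of 22. The lower gene was the unnamed locus Gm37949 (-2.08 ± 0.41, adjusted p = 0.00387), named after its value was seen. Lyve1, a marker of vessel-associated macrophages and lymphatics, did not pass (-1.54 ± 0.40, adjusted p = 0.111, below every PBS library in 5 of 6), nor did Lmtk3, Cckar and Dusp19. Of a panel of 14 inflammatory, glial and dopaminergic genes fixed in advance, 12 could be tested; C1qa, C1qb, C3, Cybb and Tyrobp rose and the others did not pass, among them the dopaminergic genes Th (-0.24 ± 0.16) and Slc6a3 (-0.07 ± 0.17). Il1b and Tnf were too low to test.

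Among the 37 gene lists fixed in advance, LPS moved 19 in wild-type mice by camera with a preset correlation, and 12 of them also with an estimated correlation. Antigen presentation had 4 of 15 members called higher and 7 higher when adjusted over the list alone (median log2 fold change 0.44, camera adjusted p = 2.37e-21, adjusted p = 0.000249 with an estimated correlation). Complement had 4 of 15 called higher and 5 adjusted over the list alone (median 0.36, camera adjusted p = 3.21e-14). The phagosome and NADPH oxidase list had 3 of 16 called higher and 8 adjusted over the list alone (median 0.57, camera adjusted p = 2.02e-13). Of 20 homeostatic microglia genes, 3 were called higher, 7 adjusted over the list alone (median 0.05, camera adjusted p = 8.09e-08). Of 21 reactive astrocyte genes, 0 were called by edgeR (4 adjusted over the list alone) while the list passed camera (median 0.26, camera adjusted p = 8.09e-08, adjusted p = 0.0044 with an estimated correlation). Lists of disease-associated microglia, interferon response, cytokines, acute phase, endothelium, lysosome and peripheral leukocytes also passed upward both ways. The lists for oligodendrocytes (adjusted p = 0.382 with an estimated correlation), pericytes (0.0842), fibroblasts (0.0753), extracellular matrix (0.122) and cerebellum (0.333), all upward, lost their camera call, as did the downward lists of glucocorticoid-responsive (0.333) and olfactory bulb genes (0.46).

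In SIGLEC11 mice, LPS raised the same kinds of transcripts. Cybb rose from 1.23 ± 0.618 to 4.94 ± 1.65 CPM (n = 6 and 6, log2 fold change 1.94 ± 0.29, adjusted p = 1.84e-05), Cd52 from 3.79 ± 1.84 to 13 ± 3.99 CPM (1.77 ± 0.24) and H2-Aa from 3.92 ± 1.63 to 12.9 ± 2.44 CPM (1.73 ± 0.24, adjusted p = 4.37e-06). B2m, the common light chain of MHC class I, rose as well (0.57 ± 0.067, adjusted p = 4.45e-08). C1qa (0.82 ± 0.12), C1qc (0.82 ± 0.10), H2-Eb1 (1.46 ± 0.22), Fcer1g (0.72 ± 0.12), the lectin Clec4a1 (2.46 ± 0.45), Ms4a6c (2.04 ± 0.35) and the copper carrier ceruloplasmin, Cp (0.78 ± 0.13), did so too. Each of these 11 genes was above every PBS library in 6 of 6 LPS libraries and kept its call in every alternative and leave-out that tested it. Saa3 had 2 counts over the PBS libraries and 262 over the LPS libraries, a ratio of 112 (95% counting interval 31.1 to 929).

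**Figure D1:**
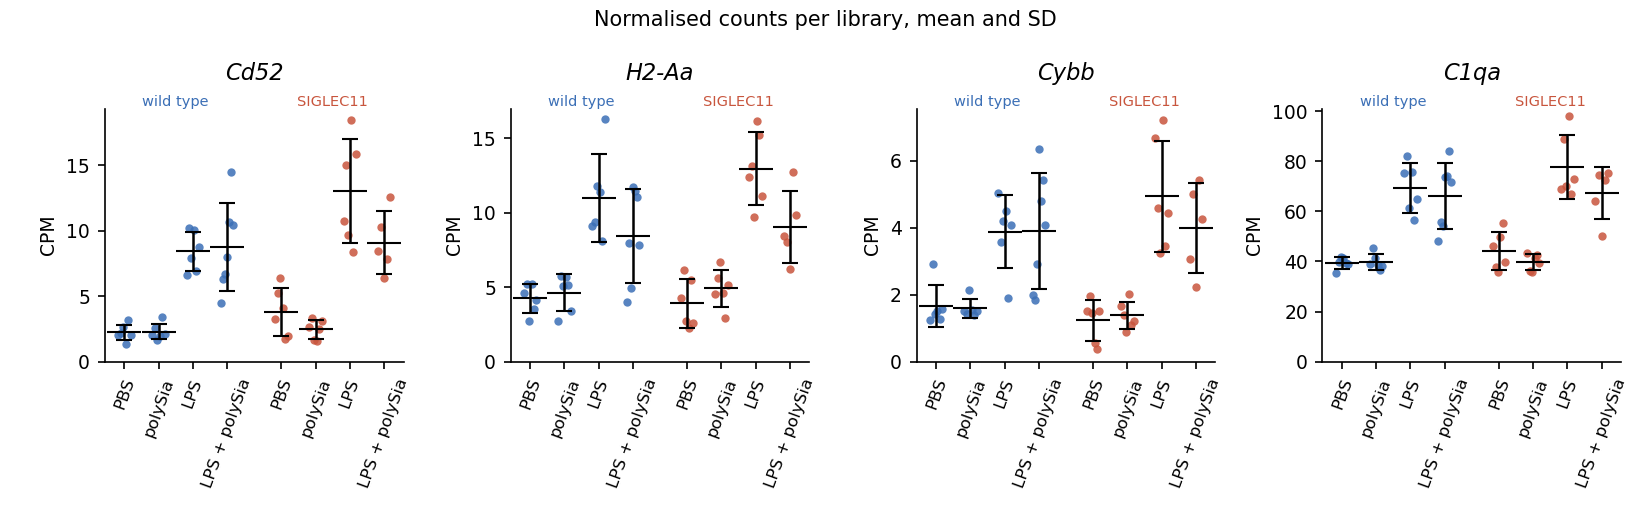
CPM of Cd52, H2-Aa, Cybb and C1qa in each library of the 8 groups, with the group mean and SD. Mean Cd52 was 2.23 in wild-type PBS and 8.42 in wild-type LPS, and 3.79 and 13 in the SIGLEC11 groups.

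LPS called 119 genes in SIGLEC11 mice, 76 higher and 43 lower, out of 2653 at unadjusted p under 0.05. Igkc (3.64 ± 0.63), the metal transporter Slc11a1 (1.86 ± 0.41), Rac2 (1.58 ± 0.34), C3 (1.43 ± 0.32, adjusted p = 0.0169), C4b (0.74 ± 0.18), Psmb8 (0.79 ± 0.20), the filament protein vimentin, Vim (0.59 ± 0.13), C1qb (0.44 ± 0.10) and Tyrobp (0.52 ± 0.11) also passed, each above the PBS mean in 6 of 6 LPS libraries, with calls lost in some or most alternatives. The calls of C4b and Psmb8 held in 9 of 21 and 10 of 21 settings, and the others in at least 15. Lyve1 fell from 2.55 ± 1.61 to 0.846 ± 0.471 CPM (-1.57 ± 0.39, adjusted p = 0.036, below the PBS mean in 6 of 6). Clec18a (-1.33 ± 0.35), Haus8, Otub2, Exosc8, Tmem14a (-0.41 ± 0.087, adjusted p = 0.00741) and Ogfod2 fell too. In the settings that tested them, the calls held in 10 of 20 for Lyve1, 7 of 21 for Clec18a and 6 of 21 for Haus8. They held in 10 of 21 for Otub2, 17 of 21 for Exosc8, 17 of 22 for Tmem14a and 12 of 21 for Ogfod2. The compared groups also differed on the first principal component (medians of 11.155 with PBS and -9.125 with LPS). The number of lower calls moved with single SIGLEC11 PBS libraries: 2 lower genes were called without library 4 and 3 without library 5, against 202 without library 1 and 188 without library 2. In total 365, 326, 38 and 44 genes were called without PBS libraries 1, 2, 4 and 5, and 54, 57 and 71 without LPS libraries 1, 5 and 6. Of the panel, C1qa, C1qb, C3, C4b, Cybb and Tyrobp rose, and the other 6 tested members, Th (0.20 ± 0.17) and Slc6a3 (-0.16 ± 0.17) among them, did not pass.

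In SIGLEC11 mice LPS moved 15 lists by camera, of which 13 also passed with an estimated correlation. Antigen presentation had 7 of 15 members called higher and 11 adjusted over the list alone (median log2 fold change 0.85, camera adjusted p = 9.48e-22, adjusted p = 0.000235 with an estimated correlation). Complement had 6 of 15 called higher and 10 adjusted over the list alone (median 0.44, camera adjusted p = 4.35e-14), and phagosome and NADPH oxidase 4 of 16 and 11 (median 0.64, camera adjusted p = 1.25e-11). Of 21 reactive astrocyte genes 3 were called higher, Cp, Vim and Psmb8, and 13 adjusted over the list alone (median 0.50, camera adjusted p = 2.23e-11). Of 20 homeostatic microglia genes 5 were called higher, with 9 higher and 1 lower adjusted over the list alone (median 0.25, camera adjusted p = 5.33e-08). The short list of cytokines and chemokines had 2 of 5 called higher and 3 adjusted over the list alone (median 0.84, camera adjusted p = 2.63e-05). Acute phase genes had 1 of 11 called higher and 8 adjusted over the list alone (camera adjusted p = 8.14e-09). Disease-associated microglia, endothelium, pericyte, extracellular matrix, lysosome and peripheral leukocyte genes were higher both ways. Nuclear oxidative phosphorylation genes had 3 of 22 called lower and 6 adjusted over the list alone; camera called the list downward with a median of -0.06 and a mean of 0.02 (camera adjusted p = 0.02), and it lost the call (adjusted p = 0.372 with an estimated correlation), as did interferon response (adjusted p = 0.0836 with an estimated correlation).

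The genotypes shared most of the genes that rose with LPS in wild-type mice. Of 26 genes higher in wild-type mice and 76 higher in SIGLEC11 mice, 23 were the same genes, where 0.119 would be shared by chance, and all 26 had a positive log2 fold change in SIGLEC11 mice. Of the 1 and 43 lower genes 0 were shared, and over all 16619 genes the log2 fold changes had a Pearson correlation of 0.154. The test of whether the LPS effect differed between genotypes called 0 genes by edgeR, DESeq2 and limma, with 1819 genes at unadjusted p under 0.05 and a smallest adjusted p of 0.35. Cybb, with mean rises of 1.24 and 1.94, differed by 0.71 ± 0.42 (unadjusted p = 0.0964, edgeR). Casz1 (0.90 ± 0.22) and Ttyh3 (0.37 ± 0.091) had the smallest unadjusted p-values among the genes higher in this term and did not pass. No list passed camera in this term (smallest adjusted p = 0.0951), while 7 did with 2 surrogate variables and 10 with 5 libraries left out together, among them glucocorticoid-responsive genes higher (median 0.26, adjusted p = 0.011 and 0.000677) and nuclear oxidative phosphorylation lower (median -0.09, adjusted p = 0.000354 and 0.00194). With an estimated correlation 0 passed (smallest adjusted p = 0.828).

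In wild-type mice given LPS, no LPS-raised transcript passed for polySia. Complement C1qa stood at 69.4 ± 9.88 CPM with LPS and 66 ± 13.2 CPM with LPS and polySia (n = 6 and 7, log2 fold change -0.07 ± 0.11). Cybb (0.01 ± 0.25) and C3 (0.32 ± 0.29) did not pass, and none of the 12 tested panel genes passed. LPS with polySia called 0 genes against LPS by edgeR, DESeq2 and limma, with 707 genes at unadjusted p under 0.05 and a smallest adjusted p of 0.976. The 707 genes are fewer than would be expected with no effect. Genes with the smallest unadjusted p-values, none passing, were Csgalnact1 (0.43 ± 0.10, above the LPS mean in 7 of 7), Dnajc10, Frat1 and Nav3 upward and Zfp51 (-1.04 ± 0.27, below in 6 of 7), Slc16a12, Cntn6 and Adssl1 downward. H2-Eb1 stood at 8.96 ± 2.48 and 6.36 ± 1.69 CPM (-0.49 ± 0.19, below the LPS mean in 7 of 7, not passing), and the interferon-induced Isg15 at 2.62 ± 0.3 and 1.54 ± 0.65 CPM (-0.72 ± 0.30, 7 of 7, not passing). Camera called 7 lists and 0 of them held with an estimated correlation (smallest adjusted p = 0.455 with an estimated correlation): antigen presentation was lower (median -0.24, 3 of 15 members above 0, camera adjusted p = 0.00237), as were interferon response (median -0.11, camera adjusted p = 0.0134), oligodendrocyte, mitochondrially encoded and cerebellum genes (median -0.11, camera adjusted p = 0.000164), while hypothalamus and olfactory bulb genes were higher. Adjusted over the list alone, 0 members of these lists passed. With 2 surrogate variables 2 lists were called, and 3 of the 7 held with 5 libraries left out together. The compared groups also differed on the first principal component (medians of -13.1 with LPS and 15.8 with LPS and polySia). That component rose with the share of small nucleolar RNAs.

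In SIGLEC11 mice given LPS, immune transcripts lay lower with polySia without passing. The Fc receptor chain Fcer1g stood at 27.5 ± 3.86 CPM with LPS and 20.4 ± 4.17 CPM with LPS and polySia (n = 6 and 5, log2 fold change -0.43 ± 0.13, below the LPS mean in 5 of 5). Laptm5 (-0.30 ± 0.090) lay below every LPS library in 5 of 5, and H2-Aa (-0.52 ± 0.23) below the LPS mean in 5 of 5. Fcer1g and Laptm5 were named for a small unadjusted p in this comparison, and H2-Aa for one within its list. Their library counts follow from that choice. C1qa stood at 77.6 ± 12.7 and 67.4 ± 10.5 CPM (-0.20 ± 0.12), Cybb at 4.94 ± 1.65 and 3.99 ± 1.34 CPM (-0.31 ± 0.27), and C3 differed by -0.38 ± 0.31. These 3 panel genes lay below the LPS mean in 5 of 5, 3 of 5 and 5 of 5 libraries. LPS with polySia called 0 genes against LPS by edgeR, DESeq2 and limma, with 541 genes at unadjusted p under 0.05 and a smallest adjusted p of 1. The 541 genes are fewer than would be expected with no effect. Of the 12 tested panel genes 2 had a positive log2 fold change, and 0 passed. The lipid transporter Mfsd2a (0.52 ± 0.12, above the LPS mean in 5 of 5), Ncbp1, Sag and Mblac1 upward and Nr1d1 (-0.40 ± 0.11) and Ube2e2 downward were among the genes with the smallest unadjusted p-values. Camera called 5 lists and 0 held with an estimated correlation. Antigen presentation was lower (median -0.29, 1 of 15 members above 0, camera adjusted p = 3.99e-05, adjusted p = 0.231 with an estimated correlation, 0 members adjusted over the list alone). The phagosome and NADPH oxidase list was lower too (median -0.26, 4 of 16 above 0, camera adjusted p = 0.00174, adjusted p = 0.29 with an estimated correlation, 1 lower adjusted over the list alone). Glucocorticoid-responsive genes were higher as a list (median 0.27, 15 of 16 above 0, camera adjusted p = 2.46e-07, adjusted p = 0.231 with an estimated correlation). The members with the smallest p, Klf9, Mt2 and Cdkn1a, did not pass singly. The olfactory bulb list was higher too (adjusted p = 0.664 with an estimated correlation), and the cerebellum list was lower (median -0.14, 0 of 16 above 0, camera adjusted p = 3.52e-07).

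An LPS score summarised these responses without using the scored mice to choose its genes: the 27 genes called for LPS in wild-type mice scored the SIGLEC11 libraries, and the 119 called in SIGLEC11 mice scored the wild-type libraries, as a mean log2 difference from the PBS group of the same genotype. In SIGLEC11 mice the score was 1.19 ± 0.22 with LPS (SD, n = 6; exact two-sided permutation p = 0.00216 against PBS, the smallest possible) and 0.89 ± 0.29 with LPS and polySia (n = 5, exact permutation p = 0.00216 against PBS). The score with polySia was 75.4% of that with LPS, a difference of -0.29 (95% interval -0.65 to 0.035, exact permutation p = 0.0758). In wild-type mice it was 0.42 ± 0.12 with LPS (n = 6) and 0.35 ± 0.19 with LPS and polySia (n = 7), 82.7%, a difference of -0.07 (95% interval -0.28 to 0.13, exact permutation p = 0.424). The scores of the genotypes use different genes, and their difference was not tested. The wild-type score rests on the 119 SIGLEC11 calls, of which 24 held in every setting. Their 43 lower genes depended on single SIGLEC11 PBS libraries. With the 50 genes of smallest p in SIGLEC11 mice the wild-type difference was -0.13 (exact permutation p = 0.369). It was -0.10 with only the genes that rose (exact permutation p = 0.414) and -0.025 with genes called by DESeq2 (exact permutation p = 0.683). PolySia without LPS left the score at 0 ± 0.058 in SIGLEC11 mice and 0.032 ± 0.054 in wild-type mice. The difference in SIGLEC11 mice passed p of 0.05 with the 50 (-0.24, exact permutation p = 0.0498) or 200 (-0.14, exact permutation p = 0.039) genes of smallest p in wild-type mice. It also passed without LPS library 3 (-0.34, exact permutation p = 0.0397), LPS library 5 (-0.34, exact permutation p = 0.0476) or the unnumbered LPS with polySia library (-0.35, exact permutation p = 0.0476). It did not pass without any other single library (8 fits, exact permutation p = 0.0524 to 0.171, with -0.17 and 0.171 without LPS with polySia library 4). Nor did it pass with genes called by DESeq2 (exact permutation p = 0.0606), only the genes that rose (0.0801), RLE size factors (0.0779) or 5 libraries left out together (-0.24, exact permutation p = 0.115).

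**Figure D2:**
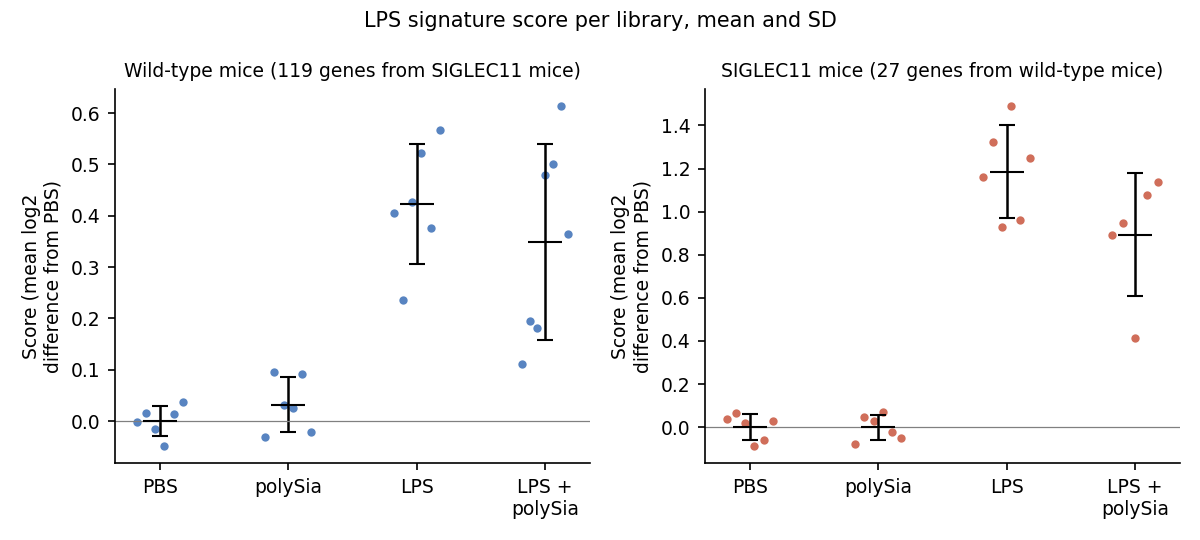
LPS score, the mean log2 difference from the PBS group, of each library in the 8 groups, with group mean and SD. The SIGLEC11 LPS with polySia libraries ran from 0.41 to 1.14 and the SIGLEC11 LPS libraries from 0.93 to 1.49.

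The polySia effect on LPS was compared between genotypes directly. The test called 0 genes by edgeR, DESeq2 and limma, with 562 genes at unadjusted p under 0.05 and a smallest adjusted p of 1. The 562 genes are fewer than would be expected with no effect. All 12 tested panel genes had a log2 fold change below 0 in this term, that is, a lower polySia effect in SIGLEC11 mice, and 0 passed. These genes were measured in the same libraries, so their directions are not independent of each other. The wild-type groups of this term also differed on the first principal component (medians of -13.1 with LPS and 15.8 with LPS and polySia). The microglial marker Tmem119 differed by -0.38 ± 0.14 and the microglial adaptor Abi3 by -0.79 ± 0.20, neither passing, and Mgmt (1.46 ± 0.42) and Csgalnact1 (-0.63 ± 0.15) had some of the smallest unadjusted p-values. Camera called 6 lists, and 0 of them with an estimated correlation (smallest adjusted p = 0.996 with an estimated correlation).

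Wild-type mice given LPS with polySia showed the LPS response against PBS. C3 rose from 0.604 ± 0.241 to 2.44 ± 1.06 CPM (n = 6 and 7, log2 fold change 2.00 ± 0.35, adjusted p = 0.000625), Cd52 to 8.74 ± 3.38 CPM (1.97 ± 0.26, adjusted p = 2.93e-06) and Lyz2 to 23.5 ± 7.38 CPM (1.30 ± 0.18), each above every PBS library in 7 of 7. Epsti1 (1.37 ± 0.29), C1qa (0.75 ± 0.11), C1qc (0.64 ± 0.099), Aif1 (0.77 ± 0.14), Ctss (0.63 ± 0.079) and Tyrobp (0.60 ± 0.10) rose in 7 of 7 too, and these 9 genes kept their calls in all 23 alternatives and leave-outs. Cybb (to 3.91 ± 1.73 CPM), Tlr2 (1.75 ± 0.41), Igkc, Ncf1, H2-Ab1, H2-Eb1, Cd74 and C1qb rose with calls lost in some or most. The call of Ncf1 held in 9 of 23 settings, that of Cybb in 12 and that of H2-Eb1 in 22. Saa3 had 206 counts, at least 59.7-fold higher. In all 37 genes were called, 34 higher and 3 lower, out of 1456 at unadjusted p under 0.05. The lower genes were Fkbp14 (-0.67 ± 0.15), Adssl1 (-0.63 ± 0.14) and, named after its value was seen, Ube2t (-1.71 ± 0.38). The count was 23 without PBS library 3, 23 without LPS with polySia library 4 or 5 and 20 without library 6. Of 13 lists called by camera, complement (median 0.37, 4 of 15 called higher, 6 adjusted over the list alone, adjusted p = 0.00721 with an estimated correlation), phagosome and NADPH oxidase (0.00721), homeostatic microglia (0.00289), antigen presentation (0.0463) and acute phase (0.0463) also passed with an estimated correlation.

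SIGLEC11 mice given LPS with polySia also had higher immune transcripts than PBS mice. Ms4a6c rose from 1.1 ± 0.54 to 5.38 ± 1.98 CPM (n = 6 and 5, log2 fold change 2.27 ± 0.35, adjusted p = 0.000147) and C1qc by 0.68 ± 0.11, each above every PBS library in 5 of 5 and kept in every setting. Saa3 had 148 counts, a ratio of 84.1 (95% counting interval 23.3 to 695) to PBS. In all 66 genes were called, 49 higher and 17 lower, out of 2601 at unadjusted p under 0.05. Cybb (1.63 ± 0.31), Gata2 (1.35 ± 0.24), Ms4a6b (1.51 ± 0.29), H2-Aa (1.21 ± 0.25), H2-Eb1, B2m (0.43 ± 0.070), C1qa (0.62 ± 0.12), Cp (0.72 ± 0.14), Igkc, Clec4a1, S1pr3 and Fam78a rose with calls lost in some or most alternatives. The calls of Cybb, Gata2, Ms4a6b, B2m, C1qa and Cp held in 20 of 21 settings. Those of S1pr3, Clec4a1 and Fam78a held in 7 of 21, 8 of 20 and 10 of 21. Pvalb, a calcium-binding protein on the inhibitory neuron and cerebellum lists, fell (-0.32 ± 0.064, adjusted p = 0.00664, below every PBS library in 5 of 5) and kept its call in all 21 settings, while Kif21b (-0.44 ± 0.099), Pik3r3, Tesc, Spr, Inpp5a, Tmem151b and Mgat4b fell with calls lost in some or most. Of these, Inpp5a kept its call in 18 of 21 settings, Spr in 9 and Mgat4b in 8. The cerebellum list was lower (median -0.14, 5 of 16 above 0, camera adjusted p = 0.00741, adjusted p = 0.324 with an estimated correlation). The count was 210, 187, 22 and 33 without PBS libraries 1, 2, 4 and 5, 39 and 43 without LPS with polySia libraries 4 and 5, and 20 without the unnumbered one. Lower calls numbered 1 with 2 surrogate variables or only the compared groups, 2 with 5 libraries left out together and 65 with DESeq2. The groups also differed on the first principal component (medians of 11.155 with PBS and -7.78 with LPS and polySia). Of 17 lists called by camera, 8 held with an estimated correlation, upward: antigen presentation (median 0.67, 6 of 15 called higher, 9 adjusted over the list alone, camera adjusted p = 5.04e-10), complement, phagosome, homeostatic microglia, cytokines, acute phase, reactive astrocytes and pericytes. Without any shared control library, 17 of the 34 and 49 genes higher in the wild-type and SIGLEC11 mice were the same, where 0.1 would be shared by chance. Of the 3 and 17 lower genes 0 were the same, and over all genes the log2 fold changes had a Pearson correlation of -0.069.

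Few transcripts differed between wild-type mice given polySia without LPS and those given PBS. The cold-inducible RNA-binding protein Cirbp rose from 58.1 ± 4.92 to 81.1 ± 6.08 CPM (n = 6 and 6, log2 fold change 0.48 ± 0.094, adjusted p = 0.0401), and Inhba, a subunit of activin, fell from 18.7 ± 4.43 to 11.2 ± 1.32 CPM (-0.74 ± 0.15, adjusted p = 0.0401), each beyond every PBS library in 6 of 6. They were the 2 genes called, out of 1032 at unadjusted p under 0.05. Each kept its call in 9 of 22 settings and lost it without most single libraries: 1 gene was called without PBS library 5 or polySia library 6, and 0 by edgeR without any other of the 12. The clock-linked genes Ciart (1.10 ± 0.23) and Bhlhe41 (0.50 ± 0.10), and Inmt (1.05 ± 0.24), were above every PBS library in 6 of 6 and did not pass. Camera called 4 lists, immediate early genes (median 0.41, 1 higher and 1 lower of 18 adjusted over the list alone, camera adjusted p = 0.000524), olfactory bulb (median 0.30) and oligodendrocytes (median 0.12) upward and striatum downward (median -0.06). None held (smallest adjusted p = 0.671 with an estimated correlation). None of the 12 tested panel genes passed.

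In SIGLEC11 mice, polySia without LPS called 1 gene out of 2433 at unadjusted p under 0.05. The dopamine receptor Drd2 fell from 51.8 ± 10 to 37.7 ± 3.18 CPM (n = 6 and 6, log2 fold change -0.45 ± 0.087, adjusted p = 0.0439, edgeR, below the PBS mean in 6 of 6), and the call held in 9 of 22 settings. The count was 50 without PBS library 1, 17 without PBS library 2, 2 without polySia library 2 and 0 by edgeR without PBS libraries 4, 5 or 6 or polySia libraries 1, 3, 5 or 6. Immediate early genes were higher as a list: 0 of 18 were called by edgeR over all genes, while 15 higher and 1 lower passed adjusted over the list alone (median 0.61, camera adjusted p = 1.41e-10, adjusted p = 0.353 with an estimated correlation). The compared groups also differed on the first principal component (medians of 11.155 with PBS and -12.45 with polySia), which rose with the share of small nucleolar RNAs. The list passed camera with 2 surrogate variables (adjusted p = 1.11e-17) and with 5 libraries left out together (adjusted p = 2.54e-14). Among its genes, Nr4a1 stood at 17.6 ± 9.68 CPM with PBS and 61.7 ± 19.7 CPM with polySia (1.77 ± 0.41), Junb differed by 1.08 ± 0.27 and Dusp1 by 0.88 ± 0.22. Sik1 (1.45 ± 0.32) and, from the hypothalamus list (camera adjusted p = 0.0253, adjusted p = 0.353 with an estimated correlation), Oxt (1.19 ± 0.33) did not pass either. None of the 12 tested panel genes passed.

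Between the genotypes over all treatments, 127 genes were called, 56 higher and 71 lower in SIGLEC11 mice, out of 1948 at unadjusted p under 0.05. The mitochondrial ribosomal proteins Mrpl46 and Mrps11 were lower: Mrpl46 stood at 31.6 ± 3.09 CPM in wild-type (n = 25) and 14.2 ± 2.52 CPM in SIGLEC11 mice (n = 23; log2 fold change -1.16 ± 0.056, adjusted p = 7.48e-25), and Mrps11 at 13.5 ± 2.32 and 7.32 ± 1.45 CPM (-0.89 ± 0.074). The selenoprotein Selenos stood at 89.9 ± 6.39 and 59.7 ± 5.14 CPM (-0.58 ± 0.034, adjusted p = 4.68e-21). Mrpl46 and Selenos were below every wild-type library in 23 of 23 SIGLEC11 libraries and Mrps11 in 21. The metalloprotease Adamts17 (0.51 ± 0.10) and C1qtnf4 (0.30 ± 0.051) were higher and Idnk (-0.33 ± 0.059) was lower; these 6 genes kept their calls in every setting. Nup35 (0.34 ± 0.085), Plek, Dapk3, Arrdc3, Ift88 and Cirbp (0.25 ± 0.047) were higher and Ptges3l (-0.47 ± 0.091), Uncx, Ephb3 and Wdr90 lower, with calls lost in some or most. The call of Wdr90 held in 27 of 56 settings and that of Arrdc3 in 39 of 57. Nuclear oxidative phosphorylation was the list that passed camera (median -0.04, 1 of 22 called lower, Ndufb5 at -0.13 ± 0.028; 5 lower adjusted over the list alone; camera adjusted p = 0.000783, adjusted p = 0.451 with an estimated correlation). C3 (0.66 ± 0.18, adjusted p = 0.0532) and the other tested panel genes did not pass, and 80 genes were called without SIGLEC11 LPS with polySia library 3. The 127 calls also included, named outside the rule, the locus CT010467.1 with 5.26% of all counts, mt-Rnr2 and mt-Nd4. The share of counts in ribosomal RNA was 3.81% to 6.52% in wild-type and 4.56% to 6.67% in SIGLEC11 libraries. In the PBS groups it was 4.249% to 4.795% and 4.612% to 6.669%. Whether this share affected the genotype calls was not tested.

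Chromosome 7 held 26 of the genotype calls, against at most 12 on another chromosome (GRCm38 coordinates from GENCODE M21). Beside these calls, 1266 tested genes were not called on chromosome 7 and 1208 on chromosome 11, which held the 12. The small mitochondrial genome had 2 called and 22 not called. A segment from 54835498 to 67759742, bounded by the called genes themselves, held 21 called of 78 tested genes (26.9%), 10 higher and 11 lower, against 106 of 16541 elsewhere (0.641%). It held Selenos (66079649 to 66089405), Adamts17, the synaptic-receptor subunit Gabrg3 (0.25), the ubiquitin ligase Ube3a (0.11), Luzp2 (0.18), Synm (0.24), Snrpa1 (-0.24) and Tm2d3 (-0.20). The neighbours Mrpl46 (78775236 to 78783531) and Mrps11 (78783119 to 78792989), which overlap, lay outside the segment, as did the called locus Gm39041 (start 79299025, -0.48). They lay outside by a fixed limit on the gap between the starts of called genes. The last called gene in the segment, Synm, started at 67730160 and the next, Mrpl46, at 78775236. Whether these genes belong to the same inherited stretch was not tested.

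**Figure D3:**
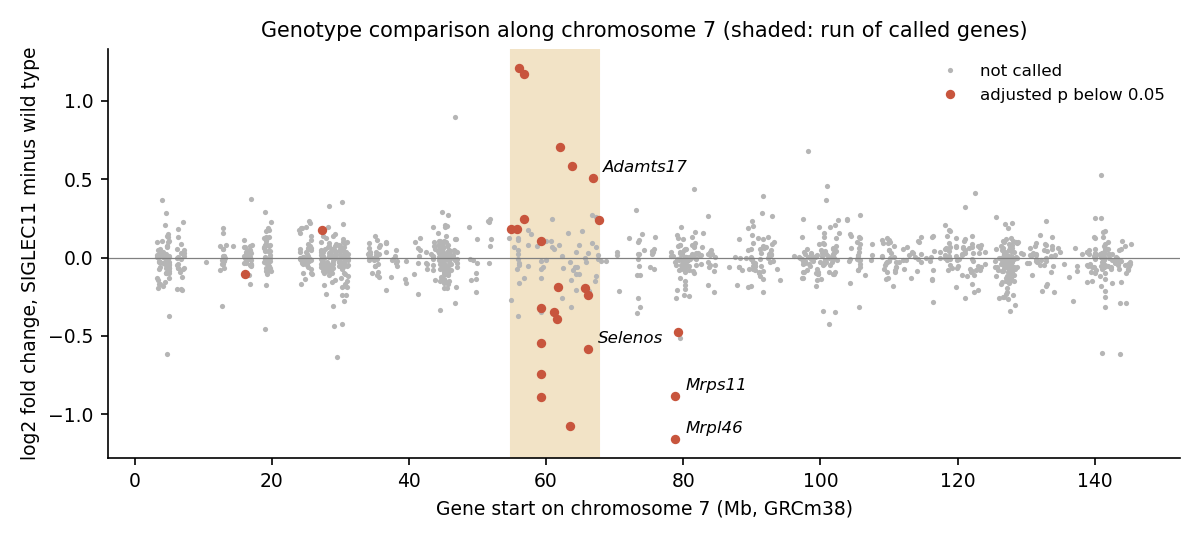
Log2 fold change of SIGLEC11 against wild type for the tested genes of chromosome 7, by position in Mb, with called genes marked and the segment from 54.8 to 67.8 Mb shaded. The segment held 21 of the 26 called genes of the chromosome.

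Libraries differed along a first principal component that held 18.4% of the variance. Its group medians were 15.8 in wild-type LPS with polySia and 11.2 in SIGLEC11 PBS, against -14.0 to -7.78 in the other 6 groups. Wild-type LPS library 2 (51.6), wild-type LPS with polySia libraries 2 (33.2) and 3 (36.7) and SIGLEC11 PBS libraries 4 (61.4) and 5 (46.1) stood apart. The component rose with the share of counts in small nucleolar RNAs (Spearman correlation 0.781 over the 48 libraries), and SIGLEC11 PBS library 5 had the lowest total, 5453797 counts. Without them 40 genes were called for LPS in SIGLEC11 mice, 39 higher and 1 lower.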

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

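The tests of single libraries and of differences between genotypes were all set before the results were seen. Of 128 groups of values tested for a library far from the rest of its group, 9 had one, where about 1 in 20, or 6.4, would by chance.

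Lcn2, an acute-phase protein, was high in single LPS-treated animals. It reached 14.6 CPM in wild-type LPS with polySia library 6 (the others 0.399 to 4.25), 8.43 CPM in SIGLEC11 LPS with polySia library 3 (0.678 to 1.59) and 6.96 CPM in wild-type LPS library 4 (0.719 to 1.97).

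Microglial genes also had single high or low libraries. Cybb stood at 2.93 CPM in wild-type PBS library 2 (the others at most 1.58) and at 2.15 CPM in wild-type polySia library 3 (1.41 to 1.56). Trem2 stood at 14.6 CPM in wild-type LPS library 2 (10.8 to 11.3), and Cd68 at 7.33 CPM in wild-type polySia library 6 (5.22 to 5.94). Tyrobp was low in SIGLEC11 LPS with polySia library 4, at 12.4 CPM (17.6 to 19.6), which is also the library with the lowest LPS score of its group, 0.41. Tyrobp is among the 27 genes of that score, so the low score is not a separate observation. The first principal component was 8.65 in SIGLEC11 LPS library 2, against -14.3 to -7.64 in the others of the group.

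For 6 lists the polySia effect on LPS differed between genotypes by camera, and 0 held with an estimated correlation (adjusted p = 0.996 for each). Homeostatic microglia genes were lower in this term (median log2 difference -0.13, camera adjusted p = 0.0266), and oligodendrocyte (0.13, camera adjusted p = 0.0266), glucocorticoid-responsive (0.15, camera adjusted p = 0.0266) and nuclear oxidative phosphorylation genes (0.08, camera adjusted p = 0.0266) were higher. Mitochondrially encoded genes (0.12, camera adjusted p = 0.0238) and brainstem genes (0.38, camera adjusted p = 0.0238) were higher too. By edgeR 0 members of these lists were called over all genes, and 0 adjusted over the list alone.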

How the results depend on the processing

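The alternative that leaves out 5 libraries together and 1 with an added covariate were chosen only after the results were seen. The other choices were made before the data were examined. None of the genes checked and none of the 89 list calls turned its direction in the alternatives run. The genes checked were those named by the rule, with panel genes only in comparisons where they passed. Panel genes that did not pass, and genes named outside the rule, such as Dbp, Per1 and Npas2, were not part of this check. Gene results stayed on the same side of the threshold in 5225 cases, 84 gained a call and 464 lost it. The 89 list calls stayed in 331 cases and were lost in 114. Lists not called before gained a call in 31 cases with 5 libraries left out, 23 with surrogate variables, 3 with the replicate block, 1 with fry and 0 with an estimated correlation.

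Calls for LPS in wild-type mice rose from 27 to 44 with 2 surrogate variables and 46 with limma, and 18 of the 27 genes kept their call in every setting that tested them. Leaving out single libraries gave 21 to 32. Calls for LPS in SIGLEC11 mice went from 119 to 30 with only the compared groups, 53 with surrogate variables, 35 with limma, 40 with 5 libraries left out and 239 with DESeq2 (41 higher, 198 lower), and 24 genes kept theirs. Single libraries gave 38 (without PBS library 4) to 365 (without PBS library 1).

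LPS with polySia against LPS stayed at 0 in wild-type mice by edgeR, DESeq2 and limma (707 genes at unadjusted p under 0.05), with 0 to 1 when single libraries were left out (1 without LPS with polySia library 5). In SIGLEC11 mice it stayed at 0 by these tools (541 at unadjusted p under 0.05) and became 1 with only the compared groups; single libraries gave 0. Both differences between genotypes stayed at 0 in all settings (1819 and 562 at unadjusted p under 0.05), by DESeq2 and limma too.

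LPS with polySia against PBS gave 20 (without LPS with polySia library 6) to 41 in wild-type mice, where 15 of 37 genes kept their call. In SIGLEC11 mice it went from 66 to 27 with only the compared groups, 11 with surrogate variables, 43 with limma, 163 with DESeq2 and 31 with 5 libraries left out; 6 genes kept their call, and single libraries gave 20 (without the unnumbered library) to 210 (without PBS library 1).

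PolySia against PBS in wild-type mice went from 2 to 18 with only the compared groups, 8 with surrogate variables, 5 with limma, 5 with DESeq2 and 4 with 5 libraries left out, and single libraries gave 0 to 1. In SIGLEC11 mice it went from 1 to 4 without a filter and 34 with DESeq2, and to 0 with the stricter filter, the compared groups, surrogate variables, limma or 5 libraries left out; single libraries gave 0 to 50 (without PBS library 1). Genotype went from 127 to 68 with surrogate variables, 198 with limma and 234 with DESeq2; 32 genes kept their call, and single libraries gave 80 (without SIGLEC11 LPS with polySia library 3) to 175. Restricting the genotype comparison to its groups was not run, since it holds all of them.

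The replicate number as a block gave 79 for LPS and 28 for LPS with polySia against PBS in SIGLEC11 mice, 0 for polySia there, and 87 list calls, 84 of them among the 89. In no comparison did every same-numbered pair of libraries correlate above 0.1 across genes, so the numbers were not taken as pairs. In wild-type LPS with polySia against LPS 4 of 6 pairs did (mean 0.129, against -0.021 for other numbers), and in wild-type against SIGLEC11 PBS 3 of 6, with 3 correlating best with their own number. Mean same-numbered correlations were -0.06 to 0.13 over the comparisons.

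The polySia difference in the SIGLEC11 LPS score passed p of 0.05 with 50 (-0.24) or 200 (-0.14) genes, and single libraries gave -0.35 to -0.17 (past it without LPS libraries 3 and 5 and without the unnumbered library). In wild-type mice single libraries gave -0.12 to -0.03. List calls went from 89 to 38 with an estimated correlation and 53 with fry. With surrogate variables and with 5 libraries left out, they went from 0 to 7 and 10 for the genotype difference in the LPS effect, from 2 to 6 and 8 for polySia in SIGLEC11 mice and from 1 to 3 and 4 for genotype. They went from 6 to 2 and 2 for the genotype difference in the polySia effect on LPS, and from 7 to 2 and 5 for LPS with polySia against LPS in wild-type mice. Why settings changed a count was not tested, beyond fewer libraries where groups or libraries were left out. At this depth, 2-fold changes were mostly recovered on simulated data, and 1.5-fold changes in 40% to 58% of genes.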

Other observations

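The tests of the inherited segment and of time of day were chosen only after the result was seen, and the chromosome 7 segment and the clock genes were picked out for their values.

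The clock genes Ciart, Dbp and Per1 lay higher in polySia mice without LPS, in both genotypes, without passing. Ciart stood at 9.99 ± 1.95 CPM in wild-type PBS and 21.4 ± 2.97 CPM with polySia, and at 10.7 ± 3.48 and 22.2 ± 3.45 CPM in SIGLEC11 mice. Dbp stood at 67.6 ± 11.5 and 112 ± 17.3 CPM and at 72.9 ± 16.1 and 116 ± 14.1 CPM (log2 fold changes 0.72 ± 0.19 and 0.68 ± 0.19), and Per1 differed by 0.54 ± 0.15 and 0.51 ± 0.15. The bHLH activator Npas2 differed the other way in wild-type mice (-0.46 ± 0.14) and by -0.08 ± 0.14 in SIGLEC11 mice.

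Over 10 clock output genes, these 3 included, the median log2 fold change was 0.29 in wild-type and 0.27 in SIGLEC11 mice. In LPS with polySia against LPS it was -0.05 and 0.03. A difference in the time of day of collection may explain the pattern and stays open: genes of the opposite phase had medians of -0.26 and -0.06, below zero in both genotypes but close to it in SIGLEC11 mice. RNA quality stays open too, since with 2 surrogate variables the output median kept 0.788 of its size in wild-type and 0.537 in SIGLEC11 mice. An effect of polySia on these genes stays open as well and was not tested, since they were picked for their values.

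The genotype calls of chromosome 7 may come from an inherited segment that differs between the lines. The tables argue against a gain of copies, since the median log2 fold change over all 78 tested genes was -0.019. With 2 surrogate variables 17 of the 21 segment calls stayed, against 24 of 106 elsewhere. The first variable followed the first principal component (Spearman correlation 0.997), so most segment calls did not depend on that component. RNA quality itself was not measured, so this does not decide on it. The inherited segment stays open: of the genes called in the PBS and polySia arms, 2 of 2 in the segment went the same way in the other arms, and so did 3 of 4 outside it. Those values met the condition set for the test, but a minimum of 5 genes was set after they were seen, because so few entered and the genes outside behaved alike.

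Other splits of the same libraries were refitted, 100 per comparison with the real one. For LPS, 2 of 100 splits gave as many as the 27 genes of wild-type mice (highest other 45). In SIGLEC11 mice 1 of 100 gave as many as the 119 genes (highest other 18). For LPS with polySia against PBS, 1 of 100 matched the 37 genes of wild-type mice (highest other 14). In SIGLEC11 mice 3 of 100 matched the 66 genes (highest other 200). For genotype 1 of 100 matched the 127 genes (highest other 6). PolySia in wild-type mice had 2 genes, matched by 1 of 100 (highest other 1), a margin too small to decide. As many genes were thus rare among the splits, which makes chance less likely. Chance is not excluded, since only 100 splits per comparison were refitted. Where 1 of 100 matched, that 1 was the real split itself. Other splits called more genes than the real one for LPS in wild-type mice (45 against 27). They also did for LPS with polySia against PBS in SIGLEC11 mice (200 against 66). For polySia in SIGLEC11 mice 7 of 100 splits gave as many as the 1 gene called (highest other 63), so chance stays open there. For the comparisons with 0 calls by edgeR, DESeq2 and limma, 100 of 100 splits gave as many, as any split must, so the splits decide nothing there: LPS with polySia against LPS in wild-type mice (707 genes at unadjusted p under 0.05; highest other 3598) and SIGLEC11 mice (541; highest other 0), and the genotype difference in the LPS effect (1819; highest other 5) and in the polySia effect on LPS (562; highest other 577). Splits that called 3598, 577, 200 or 63 genes point to a structure of the libraries other than treatment.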
